A study of Homo sapiens with 4 samples.

How the data were processed

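RNA from MDA-MB-231 cells, treated for 24 h with DMSO or with RB-BC, was sequenced in 4 libraries, 2 per group. The sample labels name the compound RB-BC and the treatment protocol names it Rib_CA, and the sources used here do not say whether these are the same. Per the labels' protocols, cells were grown with 10% serum, RNA was column-purified, and 1.4 µg of total RNA entered an mRNA library kit. The deposited table holds whole-number read counts per Ensembl gene, one column per library, with no normalization by the authors that the values show. The aligner, the counting program, its strand setting and the annotation are not given in the sources used here. Per the submitters' processing notes the genome builds are GRCm38 and mm10, which are mouse assemblies, whereas all 20263 gene identifiers in the deposited table are human Ensembl identifiers. For that reason no genomic coordinates are given, and genes are named by symbol and identifier only. Symbols came from a table of Ensembl identifiers for 19761 genes and from GENCODE release 29 for a further 463, while 39 identifiers had no symbol. Protein-coding genes made up 97.3% of the entries, and 4048 genes had no count in any library.

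Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values of single genes measure only the spread between these libraries, which may be technical. Library totals ran from 34774542 to 42786422 counts. Within-group pairs differed by far more than sampling noise (chi-square per degree of freedom of 257 for DMSO and 40.3 for RB-BC), so no pair was a single library under separate names. That does not show separate cultures. Shares of counts in single libraries carry 95% Wilson intervals, which cover counting error only because reads without molecular identifiers are not independent molecules. A gene with no count in either library of a group was given a floor of 3 counts per library, and its fold is then a lower bound.

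The main comparison used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13744. Library sizes were scaled by TMM, and a quasi-likelihood test compared the groups, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are RB-BC over DMSO with their standard error (SE). Levels are TMM-scaled CPM values, as mean ± SD over n = 2 libraries, computed here from the deposited counts. An exact permutation test on 2 against 2 libraries cannot give a two-sided p below 0.333, so single genes were tested only in the model fitted across all genes.

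The test was tried on simulated counts drawn from the means and sizes of these libraries. Of the simulated genes, edgeR recovered 18% of 50 at a 1.5-fold change and 46% of 50 at 2-fold. It recovered 98.0% of 49 at 4-fold and 100% of 50 at 8-fold. The recovered genes numbered 9, 23, 48 and 50 in that order. A further 22 calls among the 13577 genes were false. In this 1 simulated draw false calls were thus a larger share of all calls than the threshold of the main comparison is meant to allow. Far fewer genes were changed in it than the 2214 called in the data, so that share does not carry over to those calls.

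The 33 gene lists, the rule for named genes and all alternatives except one were fixed before the data were examined. Lists with at least 5 tested members (32 of 33) were compared with the other genes by camera in limma 3.58.1, at a preset inter-gene correlation of 0.01, and adjusted over the 32 lists. At that setting camera takes its spread from across the genes and not from between the libraries. A small camera p-value therefore does not show that a list would move again in other libraries. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera has only the few degrees of freedom that 4 libraries leave. After adjustment over 32 lists hardly any list could then pass, so a failure there says little about a list. The smallest such p before adjustment was 0.0115, for E2F and G1/S genes. Fry's directional test asks whether the genes of a list move one way on balance, and its mixed test whether they change in either direction. Neither compares a list with other genes. Named genes were the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 50 counts, a symbol and no overlap between groups, up to 4 members of each list with the smallest adjusted p (or 2 where none passed), and a fixed panel of p53, apoptosis and cell cycle genes. Other genes named to complete a small count, as bounds or in the closing observations were chosen after their values were seen. Some genes that the rule names are not reported here.

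Alternatives were size factors by RLE, library totals alone, no low-count filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, edgeR's exact test, the replicate number as a block, leaving out each library in turn (the lone library of a group is then assumed to vary like the pair in the other group), an adjusted p below 0.01 and a change of at least 2-fold. The removal of the 13 mitochondrially encoded genes was added after the data were seen. Figures were drawn with matplotlib 3.10.9.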

Results

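Expression was profiled by RNA sequencing in MDA-MB-231, an established human triple-negative breast cancer line, after 24 h with the vehicle DMSO or with RB-BC, a derivative of the CDK4 and CDK6 inhibitor ribociclib. The study asked how RB-BC acts on breast cancer cells, with apoptosis and the p53 pathway as its subject. The dose is not given in the sources used here. The treatment protocol in the labels calls the compound Rib_CA, and whether that is RB-BC is not stated, so the identity of the compound behind each difference rests on the sample labels. Each group held 2 libraries. DMSO 1 and DMSO 2 had 34774542 and 37754168 counts, and RB-BC 1 and RB-BC 2 had 42786422 and 42752387. The first principal component (66.6% of the variance) separated the groups, and the second (22.0%) separated DMSO 1 from DMSO 2. Mitochondrially encoded genes took 21.7% of the counts in DMSO 2 (95% Wilson interval 21.68% to 21.71%), against 8.68% in DMSO 1, 10.1% in RB-BC 1 and 10.3% in RB-BC 2. The median gene differed by 0.27 on the log2 scale between the DMSO libraries and by 0.14 between the RB-BC libraries.

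Cells treated with RB-BC had much higher transcript levels of inflammatory cytokines and lower levels of cell cycle genes. IL1B, which encodes the cytokine interleukin-1 beta, went from 2.00 ± 0.38 CPM to 179 ± 61.5 CPM (SD, n = 2), a log2 fold change of 6.49 ± 0.34 (SE). The other large rises were CXCL1 (6.47), LCN2 (6.12), CXCL2 (6.03), CXCL3 (5.89), IL6 (5.73), CSF2 (5.48), CXCL8 (5.47) and IL24 (5.39), and CSF3, with no counts in DMSO, was at least 41.1-fold higher. LCN2 had 0 and 18 counts in the DMSO libraries, and its call was lost with DESeq2 (adjusted p = 0.0673), with limma-voom (adjusted p = 0.0677) and without RB-BC 1 (4.79, edgeR adjusted p = 0.0739). Its value was 5.07 without DMSO 1, and without DMSO 2 no count is left in DMSO and no fold can be given. Among the large falls were the E2F family member E2F2 (−2.98), cyclin E2 (CCNE2, −2.83), FAM111B (−2.87), ZNF488 (−2.84), the exonuclease gene TREX2 (−4.45), ALPP (−3.56), F13A1 (−2.76) and AKAP5 (−2.52). Without RB-BC 1 ALPP, F13A1 and AKAP5 did not pass (edgeR adjusted p = 0.0554, 0.0792 and 0.145), and AKAP5 was also lost without RB-BC 2 (edgeR adjusted p = 0.0505) and without DMSO 1 (−1.71, edgeR adjusted p = 0.0548). ALPP shares sequence with close paralogs and is uncertain. The read-through gene JMJD7-PLA2G4B, with no counts in RB-BC, was at least 42.9-fold lower, and the clone-based gene AC007192.1 had 89 and 109 counts in DMSO and 0 and 2 in RB-BC; both overlap other genes or are poorly annotated and are uncertain.

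In all, 2214 of 13744 genes passed edgeR's quasi-likelihood test, 1179 of them higher and 1035 lower in RB-BC. Changes of at least 2-fold numbered 635 upward and 445 downward. The groups did not overlap for 65.2% of tested genes, where chance gives 33.3%. All 2214 called genes were among these, so leaving out 1 library could hardly reverse their signs. With library totals alone as the scaling, 790 genes were higher and 415 lower, so that 65.6% of calls were upward against 53.3% with TMM. The number of calls was 205 without RB-BC 1, 450 without RB-BC 2, 3243 without DMSO 1 and 3648 without DMSO 2, and no called gene changed sign in any of these fits, in which the pair of libraries in the other group alone sets the spread. Of the 136 named genes, 77 lost their call without RB-BC 1 and 51 without RB-BC 2, while 2 lost it without DMSO 1 and 0 without DMSO 2. Of 32 gene lists tested, 18 passed camera (11 up, 7 down), 0 passed with an estimated correlation, 11 passed fry's directional test and 28 its mixed test. The test with an estimated correlation had few degrees of freedom, so its 0 was close to fixed by the design.

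**Figure D1:**
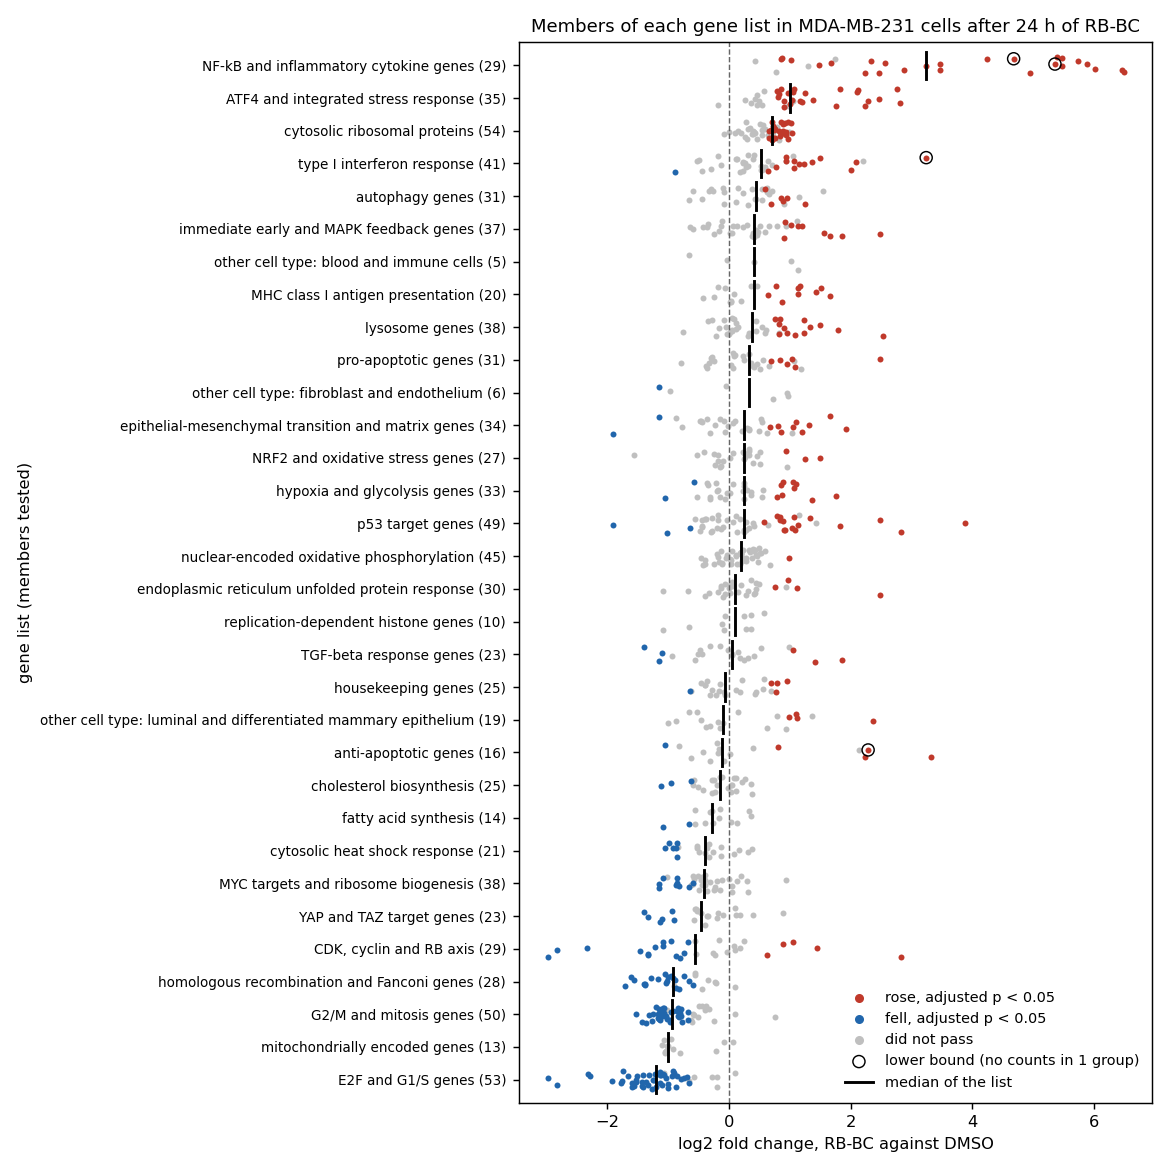
Log2 fold change (RB-BC against DMSO, x axis) of each tested member of 32 gene lists (y axis, members tested in parentheses), with red points for members that rose, blue for those that fell, grey for those that did not pass edgeR's test, circles for lower bounds of genes with no counts in 1 group, and black bars for list medians. Medians ran from −1.20 for E2F and G1/S genes to 3.24 for NF-kB and inflammatory cytokine genes.

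Of 49 p53 target genes, 16 rose and 3 fell. The largest rise was in GDF15, a stress-induced cytokine, from 8.53 ± 2.15 to 126 ± 31.1 CPM (log2 fold change 3.89 ± 0.27). CDKN1A, which encodes the CDK inhibitor p21, went from 26.2 ± 10.5 to 186 ± 30.4 CPM (2.83 ± 0.31), BBC3, which encodes the pro-apoptotic protein PUMA, rose by 2.48 ± 0.21 and SESN2, a sestrin, by 1.83 ± 0.17. SESN2 is also a member of the ATF4 and integrated stress response list, so its rise counts in both lists. The 3 p53 target genes that fell were KITLG (−1.90), TIGAR (−1.02) and PLK2 (−0.63). BAX (0.07 ± 0.20, edgeR adjusted p = 0.822) and FAS (−0.29 ± 0.20) did not pass. MDM2, a p53 target and its ubiquitin ligase, had 35.5 and 77.0 CPM in DMSO 1 and DMSO 2 and 68.5 CPM in RB-BC (0.28 ± 0.34, edgeR adjusted p = 0.590). It did not pass with all 4 libraries, and the result depended on which DMSO library was used. Without DMSO 2, the library with the large mitochondrial share, MDM2 was at 0.95. The spread in that fit comes from the RB-BC pair alone, with information shared across genes, although the DMSO libraries lay far apart for MDM2. Without DMSO 1 MDM2 was at −0.17. Adjusted over the list alone, 17 rose and 4 fell. The list's median log2 fold change was 0.24 (camera adjusted p = 5.74e-04, and adjusted p = 0.214 with an estimated correlation). Members that rose numbered 4 without RB-BC 1 and 5 without RB-BC 2, with none falling, while 4 fell without DMSO 1 and 6 without DMSO 2, and 1 fell with library totals alone.

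**Figure D2:**
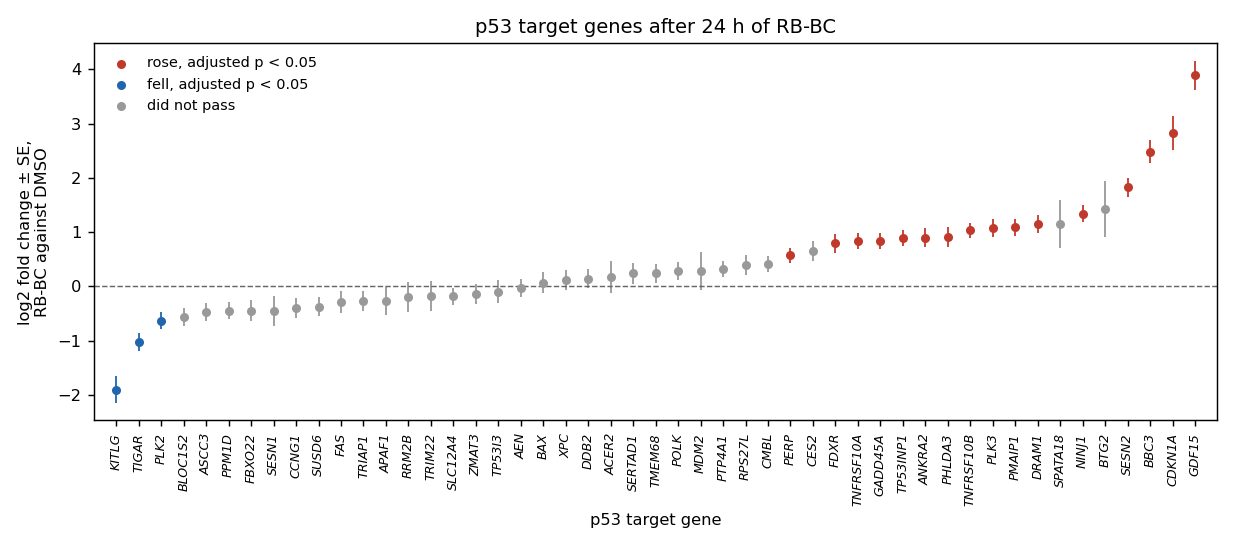
Log2 fold change ± SE (RB-BC against DMSO, y axis) of the 49 tested p53 target genes (x axis), 2 libraries per group, red for genes that rose, blue for genes that fell and grey for genes that did not pass edgeR's test. GDF15 (3.89), CDKN1A (2.83) and BBC3 (2.48) lie above the rest, and MDM2 (0.28) and BAX (0.07) lie nearer 0; MDM2 was at 0.95 without DMSO 2 and at −0.17 without DMSO 1.

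Of 31 pro-apoptotic genes, 6 rose and 0 fell, counts that were the same adjusted over the list alone. Besides BBC3 they included PMAIP1, which encodes NOXA (1.09 ± 0.15), and the death receptor genes TNFRSF10B (1.03 ± 0.14) and TNFRSF10A (0.83 ± 0.15). BBC3 and these genes are also members of the p53 target list, so their rises count in both lists. The median was 0.34 (camera adjusted p = 0.0106, and adjusted p = 0.315 with an estimated correlation), and 1 member rose with either RB-BC library left out, while 1 fell with either DMSO library left out. Among 16 anti-apoptotic genes, 4 rose and 1 fell, the same counts adjusted over the list alone. TRAF1 (3.32 ± 0.36), BIRC3 (2.23 ± 0.15) and MCL1 (0.80 ± 0.15) rose, BCL2A1, with no counts in DMSO, was at least 4.89-fold higher, and the chaperone cofactor BAG3 fell by 1.04. BIRC3 is also a member of the NF-kB and inflammatory cytokine list. BCL2 was at −0.82 ± 0.29 (edgeR adjusted p = 0.103) and passed without DMSO 2 (−1.10, edgeR adjusted p = 0.0369) and, narrowly, with DESeq2. The median of this list was −0.11 while its mean and camera's direction were upward, and it did not pass (camera adjusted p = 0.109); without DMSO 1 its adjusted p was 0.0345 and without RB-BC 1 it was 0.0469. Without DMSO 2, 3 of its members rose and 3 fell, and without RB-BC 2, 2 rose and 0 fell. MCL1 did not pass without RB-BC 1 or RB-BC 2 (edgeR adjusted p = 0.172 and 0.159).

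E2F and G1/S genes, which serve DNA replication, fell together: 46 of 53 fell and 0 rose, or 49 and 0 adjusted over the list alone. UHRF1 fell by 2.32 on the log2 scale, MCM10 by 1.91 and RRM2, a subunit of ribonucleotide reductase, by 1.74. CCNE2 went from 59.8 ± 1.41 to 8.40 ± 1.38 CPM. Of 50 G2/M and mitosis genes 36 fell (43 adjusted over the list alone) and 0 rose, among them the proliferation marker MKI67 (−1.53 ± 0.16), ANLN (−1.35) and the kinesin KIF11 (−1.27). Of 28 homologous recombination and Fanconi genes 20 fell (23 adjusted over the list alone), with BRIP1 at −1.71, XRCC2 at −1.61 and FANCA at −1.55. Median log2 fold changes were −1.20, −0.93 and −0.91, with camera adjusted p = 4.65e-45, 3.2e-23 and 3.75e-14. In the same order, adjusted p = 0.214, 0.214 and 0.259 with an estimated correlation. Without RB-BC 1 the members that fell numbered 9, 0 and 2, and without RB-BC 2 they numbered 20, 4 and 5, while the list medians stayed between −0.84 and −1.20. Without RB-BC 1 the G2/M list had 1 call, a rise, and FANCA did not pass (edgeR adjusted p = 0.0532). With library totals alone 22 G2/M and 8 homologous recombination genes fell.

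In the CDK, cyclin and RB axis, 14 of 29 genes fell and 5 rose (16 and 5 adjusted over the list alone). E2F8 fell by 2.34, the RB-related gene RBL1 by 1.33 and E2F1 by 1.08. The 5 that rose were CDKN1A, CCND2 (1.45), CDKN1C (1.06), E2F5 (0.89) and CDK4 (0.63 ± 0.13), of which CDKN1A and CDKN1C encode CDK inhibitors. CDK6 (−0.26 ± 0.19), RB1 (−0.16 ± 0.14) and cyclin D1 (CCND1, −0.53 ± 0.18, edgeR adjusted p = 0.0932) did not pass, though CDK6 did without DMSO 2 (−0.48, edgeR adjusted p = 0.0446) and CCND1 without DMSO 1 (−0.66, edgeR adjusted p = 0.0330) and with DESeq2 (adjusted p = 0.0290). The call of CDK4 was lost with library totals alone (edgeR adjusted p = 0.0661), and without RB-BC 1 RBL1, E2F1 and CDK4 did not pass (edgeR adjusted p = 0.0713, 0.0895 and 0.244), nor did E2F1 and CDK4 without RB-BC 2 (edgeR adjusted p = 0.0959 and 0.209). The median was −0.56 (camera adjusted p = 9.52e-06, and adjusted p = 0.214 with an estimated correlation). Without RB-BC 1 there were 3 falls and 1 rise, without RB-BC 2 there were 4 and 1, and with library totals alone 10 and 1. Of 10 replication-dependent histone genes, 0 passed edgeR's test, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.992); H2AC11 was at −1.09 ± 0.44 and H2BC5 at 0.58 ± 0.29, which passed without DMSO 2 (0.96, edgeR adjusted p = 0.0462).

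Genes of the integrated stress response, which the transcription factor ATF4 drives, rose: 24 of 35 rose and 0 fell, or 31 and 0 adjusted over the list alone. CEBPB went from 52.2 ± 2.36 to 356 ± 52.6 CPM (2.77 ± 0.17), and CTH, of cysteine synthesis, rose by 2.47 and the stress regulator NUPR1 by 2.28. The median was 1.01 (camera adjusted p = 9.83e-24, and adjusted p = 0.214 with an estimated correlation), with 8 rises without RB-BC 1 and 11 without RB-BC 2. Of 30 genes of the endoplasmic reticulum unfolded protein response 4 rose, also adjusted over the list alone, namely ERN1 (2.48), XBP1 (1.12), DNAJB9 (0.98) and HERPUD1 (0.76). That list did not pass camera (adjusted p = 0.0523), but did without DMSO 2 (adjusted p = 0.00907), without RB-BC 2 (adjusted p = 0.0438), with no low-count filter (adjusted p = 0.0337), with a mean of at least 50 counts (adjusted p = 0.0298) and with mitochondrially encoded genes removed (adjusted p = 0.0495). Its members numbered 7 rises and 3 falls without DMSO 1, 8 rises and 1 fall without DMSO 2, and 1 rise with either RB-BC library left out. Of 21 cytosolic heat shock genes 6 fell (7 adjusted over the list alone) and 0 rose, with HSPA8 at −0.85 and DNAJA1 at −0.86. HSPA1A (−0.86) and HSPA1B (−0.91) are near-identical copies and uncertain. The list's median was −0.39 (camera adjusted p = 7.49e-04, and adjusted p = 0.315 with an estimated correlation), and by edgeR's test 0 members fell with either RB-BC library left out, while 11 fell and 2 rose without DMSO 2. The ferritin genes FTH1 (2.83-fold) and FTL (2.38-fold) and TRIM16L (1.91-fold) were the 3 of 27 NRF2 and oxidative stress genes that rose, as they were adjusted over the list alone, and the list did not pass camera (adjusted p = 0.138). By edgeR's test 5 rose without DMSO 1, 6 rose and 1 fell without DMSO 2, 0 rose without RB-BC 1 and 1 without RB-BC 2. Of 4 metallothioneins tested, which bind metal ions, 3 rose (4 adjusted over the list alone), led by MT1X (2.63) and MT2A (1.22); they are close paralogs and were too few for a list test. MT2A and MT1E did not pass without RB-BC 1 (edgeR adjusted p = 0.122 and 0.252) or without RB-BC 2 (edgeR adjusted p = 0.0583 and 0.17), nor did MT1E with library totals alone (edgeR adjusted p = 0.0912).

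**Figure D3:**
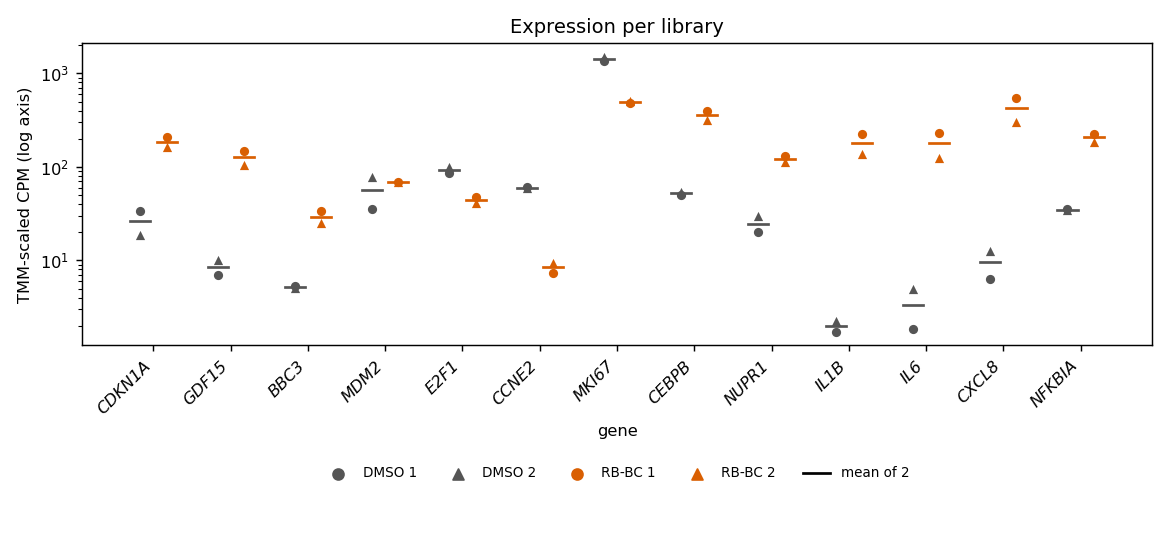
TMM-scaled CPM (y axis, log scale) of 13 genes (x axis) in DMSO 1, DMSO 2, RB-BC 1 and RB-BC 2, with a bar at the mean of the 2 libraries of a group. IL1B, IL6 and CXCL8 rose to means of 179, 178 and 421 CPM in RB-BC, CCNE2 fell to 8.40 CPM, and MDM2 overlapped between the groups.

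NF-kB and inflammatory cytokine genes had the largest list median, 3.24, with 25 of 29 higher and 0 lower (27 and 0 adjusted over the list alone). CXCL8, a neutrophil chemokine, went from 9.52 ± 4.56 to 421 ± 173 CPM and IL6 from 3.36 ± 2.16 to 178 ± 75.4 CPM. NFKBIA, which encodes the NF-kB inhibitor IκBα, rose by 2.57 ± 0.17 and IL1A by 4.25 ± 0.28. CXCL1, CXCL2 and CXCL3 are similar in sequence, and how reads were shared among them is not known. Camera gave adjusted p = 3.31e-57, and adjusted p = 0.214 with an estimated correlation; 20 members rose without RB-BC 1 and 22 without RB-BC 2. Of 41 type I interferon response genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), among them OASL (2.09), IFIH1 (2.01) and ISG15 (1.49). The median was 0.53 (camera adjusted p = 5.72e-06, and adjusted p = 0.249 with an estimated correlation), with 3 rises without RB-BC 1 and 5 without RB-BC 2, and 2 falls without DMSO 2. Of 20 genes of MHC class I antigen presentation 9 rose and 0 fell (10 and 1 adjusted over the list alone), including PSMB9 (1.43), the peptide transporter TAP1 (1.16) and HLA-B (1.14), whose family members share sequence. The median was 0.42 (camera adjusted p = 4.57e-04, and adjusted p = 0.315 with an estimated correlation), with 0 rises by edgeR's test without RB-BC 1 and 5 without RB-BC 2. Of 37 immediate early and MAPK feedback genes 9 rose and 0 fell, also adjusted over the list alone, with IER3 at 2.49, EREG at 1.66 and DUSP5 at 1.56. The median of 0.42 (camera adjusted p = 1.84e-04, and adjusted p = 0.575 with an estimated correlation) was 0.23 without DMSO 1 and 0.96 without DMSO 2, where 19 rose, and 2 rose without RB-BC 1 and 5 without RB-BC 2. DUSP5 did not pass without RB-BC 1 (edgeR adjusted p = 0.0575). Members that fell numbered 3 without DMSO 1, 1 without DMSO 2 and 1 without RB-BC 2.

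Cytosolic ribosomal protein genes were higher in RB-BC, with 25 of 54 rising and 0 falling (38 and 0 adjusted over the list alone). RPS27 rose by 1.02, RPL13 by 0.97 and RPL37 by 0.97. The median was 0.71 (camera adjusted p = 1.26e-12, and adjusted p = 0.315 with an estimated correlation). Ribosomal proteins have many processed pseudogenes, and the counting of shared reads is not known. By edgeR's test 0 rose without RB-BC 1 and 1 without RB-BC 2, at list medians of 0.61 and 0.76, and 13 rose with library totals alone. MYC targets and ribosome biogenesis genes went the other way, with 9 of 38 falling and 0 rising (12 and 0 adjusted over the list alone), among them the nucleolar genes NOP58 (−1.15), UTP15 (−1.15) and TCOF1 (−0.85), and CAD (−1.08) of pyrimidine synthesis. The median was −0.42 (camera adjusted p = 5.24e-05, and adjusted p = 0.214 with an estimated correlation), and by edgeR's test 0 fell with either RB-BC library left out, against 15 without DMSO 1 and 14, with 1 rise, without DMSO 2. With library totals alone 5 fell.

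Of 38 lysosome genes 13 rose and 0 fell (17 and 0 adjusted over the list alone), including the proton pump subunit ATP6V0D2 (2.54), the glucosidase GAA (1.24) and the cholesterol transporter NPC1 (1.09). The median was 0.38 (camera adjusted p = 1.68e-05, and adjusted p = 0.315 with an estimated correlation), with 2 rises without RB-BC 1 and 5 without RB-BC 2, and 3 falls without DMSO 1. Without RB-BC 1 GAA and NPC1 did not pass (edgeR adjusted p = 0.0657 and 0.0873), nor did NPC1 without RB-BC 2 (edgeR adjusted p = 0.0707). Of 31 autophagy genes 6 rose and 0 fell (9 and 1 adjusted over the list alone), with WIPI1 at 1.26 and GABARAP at 0.95. Their median was 0.45 (camera adjusted p = 0.00765, and adjusted p = 0.259 with an estimated correlation); 0 rose by edgeR's test without RB-BC 1 and 1 without RB-BC 2, and 10 rose with either DMSO library left out, with 1 fall without DMSO 2. In cholesterol biosynthesis 3 of 25 fell (2 adjusted over the list alone), namely HMGCS1 (−1.11), IDI1 (−0.95) and STARD4 (−0.63), and in fatty acid synthesis 2 of 14 fell (3 adjusted over the list alone), FASN (−1.08) and ACACA (−0.65). With library totals alone HMGCS1, STARD4 and ACACA did not pass (edgeR adjusted p = 0.0556, 0.154 and 0.104), nor did HMGCS1 without DMSO 1 (edgeR adjusted p = 0.0503) or STARD4 with no low-count filter (edgeR adjusted p = 0.0508). Neither list passed camera (adjusted p = 0.138 and 0.108), though without DMSO 1 they gave 0.00537 and 0.0421, with 6 members falling in each and 1 rising in the fatty acid list. Without DMSO 2 the cholesterol list had 3 falls and 1 rise and the fatty acid list 4 and 2, and the falls were 0 and 0 without RB-BC 1 and 1 and 0 without RB-BC 2.

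Of 33 hypoxia and glycolysis genes 9 rose and 2 fell (10 and 3 adjusted over the list alone), with VEGFA at 1.76, NDRG1 at 1.37 and the glucose transporter SLC2A3 at 1.08. The median was 0.24 (camera adjusted p = 0.0188, and adjusted p = 0.505 with an estimated correlation). That call was lost without DMSO 1 (adjusted p = 0.112), and by edgeR's test 5 fell without DMSO 1, 0 rose without RB-BC 1 and 2 rose without RB-BC 2. Of 45 nuclear-encoded genes of oxidative phosphorylation 1 rose, COX5B (1.00), and 0 adjusted over the list alone; the list did not pass camera (adjusted p = 0.138) but did without DMSO 1 (adjusted p = 0.0345), where 4 rose, whereas 2 rose and 3 fell without DMSO 2 and 0 rose without RB-BC 1. Of the 13 mitochondrially encoded genes 0 passed edgeR's test, also adjusted over the list alone, with a median of −0.99 (camera adjusted p = 0.0936). This value rested on the DMSO library compared: without DMSO 1 all 13 fell (median −1.63), and without DMSO 2 the median was 0.15 and 3 rose. With library totals alone the list passed camera (adjusted p = 0.0191), as it did without RB-BC 2 (adjusted p = 0.0391). MT-CYB was at −1.06 ± 0.50 and MT-ND2 at −1.06 ± 0.52.

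Of 34 epithelial-mesenchymal transition and matrix genes 9 rose and 2 fell (10 and 3 adjusted over the list alone). The cross-linking enzyme gene LOX rose by 1.67 and PLAUR by 1.20, while THBS1 fell by 1.91. The list did not pass camera (adjusted p = 0.0558) but did without DMSO 2 (adjusted p = 8.82e-04), without RB-BC 1 (adjusted p = 0.0475), with library totals alone (adjusted p = 0.0221) and with a mean of at least 50 counts (adjusted p = 0.0447). Without DMSO 1 5 of its members fell, and 2 rose without RB-BC 1, PLAUR not among them (edgeR adjusted p = 0.0950), and 4 without RB-BC 2. Of 23 TGF-beta response genes 3 rose and 3 fell, also adjusted over the list alone, with JUNB at 1.86 and CCN2 at −1.39 (camera adjusted p = 0.846). These counts were 3 and 5 without DMSO 1, 6 and 3 without DMSO 2, 0 and 0 without RB-BC 1 and 1 and 1 without RB-BC 2. Of 23 YAP and TAZ target genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), including CCN2, F3 (−1.33) and CRIM1 (−1.13). The YAP and TAZ median was −0.45 (camera adjusted p = 1.77e-04, and adjusted p = 0.348 with an estimated correlation), and 0 fell by edgeR's test without RB-BC 1 and 2 without RB-BC 2, against 11 without DMSO 1.

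Markers of other cell types were also measured. Of 19 tested luminal and differentiated mammary epithelial genes 4 rose, also adjusted over the list alone, namely ELF3 (2.37), XBP1 (1.12), ESRP1 (1.11) and CLDN4 (0.98), and the list did not pass camera (adjusted p = 0.201). Without DMSO 1 2 luminal genes fell, and 0 rose without RB-BC 1 and 1 without RB-BC 2. Of 5 tested blood and immune genes 0 passed edgeR's test, also adjusted over the list alone (camera adjusted p = 0.409), with PTPRC at 0.49 ± 0.14 and 1.08 ± 0.02 CPM in DMSO and RB-BC and CD68 at 240 ± 130 and 487 ± 22.1 CPM. CD68, which many non-immune cells express, passed without DMSO 1 (0.55, edgeR adjusted p = 0.0347), without DMSO 2 (1.72, edgeR adjusted p = 0.0065), with DESeq2 (adjusted p = 0.0171) and with edgeR's exact test (adjusted p = 0.0373). Of 6 fibroblast and endothelial genes 1 fell, COL1A1 (−1.15), as it did adjusted over the list alone, though not with either RB-BC library left out, and the list did not pass camera (adjusted p = 0.992). Among 25 housekeeping genes 4 rose and 1 fell, also adjusted over the list alone; B2M (0.78) and PGK1 (0.79) rose and VCP fell by 0.64, and the list did not pass camera (adjusted p = 0.560). Of the housekeeping genes 7 rose and 5 fell without DMSO 2, and 0 passed edgeR's test with either RB-BC library left out. With library totals alone COL1A1 and VCP did not pass (edgeR adjusted p = 0.0550 and 0.0997).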

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

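With 2 libraries per group the counts of calls followed which library was left out, and the removal of the 13 mitochondrially encoded genes was chosen after seeing the data. Against 2214 genes past the threshold (1179 higher, 1035 lower), leaving out one library gave 205 to 3648 (149 to 1888 higher, 56 to 1760 lower). With one library left out, the pair in the other group alone sets the spread, and the lone library is assumed to vary like it; the DMSO pair differed more (906 genes over 2-fold apart) than the RB-BC pair (464). Library totals alone gave 1205 calls (790 higher, 415 lower), an adjusted p below 0.01 gave 230 (151 and 79), and a change of at least 2-fold gave 1080 (635 and 445), where the stricter criteria themselves set the number. For library totals alone the cause was not tested. Counts stayed within 1.5 times the main one with RLE (2217), no filter (2109), a mean of 50 counts (2211), DESeq2 (3114), limma-voom (2281), edgeR's exact test (3088) and mitochondrially encoded genes removed (2246, of which 2208 were shared). No main call changed sign in any of these settings. That was largely fixed beforehand, since the groups did not overlap for any of the 2214 called genes, and is no separate support. The 18 list calls became 0 with an estimated correlation, where few degrees of freedom left hardly any list able to pass, and 11 with fry. The p53 list, at a median of 0.24, had an adjusted p of 0.214 by camera with an estimated correlation and 0.0317 by fry. Its median lay between 0.24 and 0.28 with any 1 library left out.

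Nothing in the labels ties the shared replicate numbers to a common day or batch, so the samples share only a number. The deviations of DMSO 1 and RB-BC 1 from their group means correlated at −0.03, the single independent value that 2 libraries per group allow, which neither shows nor excludes a pairing. With the replicate block 2114 genes passed (1152 higher, 962 lower), 1878 of them shared with the unblocked fit. Under the block the mitochondrially encoded list passed camera (adjusted p = 0.0151), and the luminal list's median was 0.0131. Of the 136 named genes the block ended 4 calls (STARD4, ACACA, VCP and CDK4) and added 1 (CD68).

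Each value that changed sign was of a list or gene that did not pass with all 4 libraries, and the cause was not tested. With one library left out, medians ran from −0.188 to 0.0617 for anti-apoptotic genes, −0.14 to 0.28 for histones, −0.33 to 0.10 for cholesterol biosynthesis, −1.63 to 0.15 for mitochondrially encoded genes, −0.14 to 0.11 for TGF-beta response, −0.0643 to 0.0549 for housekeeping, −0.22 to 0.19 for luminal and −0.31 to 0.75 for fibroblast and endothelial genes. The luminal median was also 0.0239 with library totals alone and 0.0530 with limma-voom, and the blood list's was −0.0288 with no low-count filter. Log2 fold changes ran from −1.67 to 0.0309 for MT-ND2, −0.169 to 0.946 for MDM2 and −0.135 to 0.312 for BAX, in each case lowest without DMSO 1 and highest without DMSO 2. Of the 4 omissions, MDM2 passed in the one without DMSO 2 (edgeR adjusted p = 0.0108).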

Other observations

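Of the tests below, the comparison of ribosomal protein genes with matched random lists was specified before its result was seen; the gene groups and all other tests were chosen after the data had been seen. A set of 12 genes was picked from the table for rising, namely C3, CFB, C1R, C1S, LCN2, PTX3, SAA1, SAA2, PTGS2, PTGES, CH25H and NAMPT, of which PTGS2 is also in the fixed cytokine list. By edgeR's test 11 rose, SAA1 (1.99) being the one that did not pass, and 9 rose without DMSO 1, 11 without DMSO 2, 7 without RB-BC 1 and 8 without RB-BC 2. C3, the central complement component, was at 4.44 ± 0.43, PTGS2, which encodes cyclooxygenase-2, at 4.95 ± 0.49, PTGES at 3.20 ± 0.27 and PTX3 at 2.35 ± 0.19. A second group, the cytosolic tRNA synthetases, had a median of 0.17. Its members SARS1, GARS1, AARS1 and WARS1 also belong to the fixed list of the integrated stress response, so the group is not separate from that list. Of 20 cytosolic tRNA synthetases 4 rose (SARS1, GARS1, CARS1 and AARS1, at 1.01, 1.04, 1.03 and 0.86), with camera p = 0.0463, and p = 0.518 with an estimated correlation; by edgeR's test 0 rose with either RB-BC library left out, 8 rose without DMSO 1, and 5 rose and 1 fell without DMSO 2.

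Of 11 SR splicing factor genes 7 fell, including SRSF2 (−0.90) and SRSF7 (−0.80), with a median of −0.71 (camera p = 3.6e-05, and p = 0.0648 with an estimated correlation). Of 20 hnRNP genes 11 fell, including HNRNPR (−1.08) and HNRNPA2B1 (−0.84), with a median of −0.64 (camera p = 7e-07, and p = 0.0944 with an estimated correlation). By edgeR's test 0 of either group fell with either RB-BC library left out. These families were picked after their values were seen, so the p-values describe them and are no independent test. Among the called genes 8 had read-through names, and their reads cannot be told from those of the genes they overlap. Of the mitochondrially encoded genes, MT-CO2 had 6709 and 17583 CPM of the library total in DMSO 1 and DMSO 2 and 14464 and 13284 in RB-BC 1 and RB-BC 2, so that it was higher in RB-BC than in DMSO 1 and lower than in DMSO 2, and MT-CO1 had 22428, 50237, 21795 and 23425.

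The p53 target list passed camera, though not with an estimated correlation (adjusted p = 0.214), while BAX did not pass edgeR's test and MDM2 passed only without DMSO 2 (0.946 there, −0.169 without DMSO 1). A candidate explanation is that members which also respond to ATF4 or CHOP carry the rise, since the 7 such members all rose (median 1.83). The other 42 had a median of 0.13, 9 rises and 3 falls, with camera p = 0.227, and p = 0.288 with an estimated correlation. The members left out were singled out after their values were seen, so this cannot be told apart from a p53 response in part of the list, and an effect of RB-BC on either stays open and untested. One DMSO library as the whole cause is argued against by camera, which passed upward without DMSO 1 (adjusted p = 8.11e-04, 16 rises and 4 falls) and without DMSO 2 (adjusted p = 0.00243, 20 rises and 6 falls), at the preset correlation.

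The rise of inflammatory cytokine genes might come from leukocytes among the cells, but 11 leukocyte transcripts (PTPRC, TYROBP, FCER1G, LYZ, CD14, ITGAM, CSF1R, CD3D, CD3E, CD79A and MS4A1) summed to at most 2.83 CPM in the RB-BC libraries, while IL6 alone had 234 and 128 CPM, all as CPM of the library total without TMM scaling. The 20 members of the fixed blood and immune list other than CD68, CD8A included, summed to 5.42 and 6.76 CPM in RB-BC and 4.77 and 4.58 CPM in DMSO, and CD68, left out because many non-immune cells express it, had 478 and 515 CPM in RB-BC and 160 and 295 CPM in DMSO on that scale. It might also come from one RB-BC library: of all 29 tested members 24 were over 2-fold above both DMSO libraries in RB-BC 1 and 22 (75.9%, narrowly over the bound of 75% set for this) in RB-BC 2, and without RB-BC 1 20 still rose, which argues against one library as the whole cause. The size did differ, since 26 of the 29 were higher in RB-BC 1, at a median ratio of 1.43. A response of the cells to RB-BC remains as a hypothesis, and contamination of the compound by a microbial product was not tested.

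The rise of ribosomal protein genes could reflect their short, abundant transcripts. Of 10000 random lists matched on transcript length, GC content and abundance, 0 reached the list's median of 0.71, and the highest reached 0.41. The match was imperfect, as the ribosomal genes had a median length of 1864.5 bases and 8.83 log2 CPM against 2385 and 7.67 in the matched pool. Length and GC content here are those of each gene's longest annotated transcript, which need not be the one expressed. Random members were also drawn independently, whereas genes of a list can move together. The draws therefore cannot exclude a bias from length, GC content or abundance. DMSO 2 alone does not account for the rise, since the median without it was 0.677. A treatment effect and a difference in RNA quality between groups both stay open, the latter because log2 fold changes across genes, which are not independent replicates, correlated with transcript length (Spearman's rho −0.163) and GC content (0.220).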
